A study of Mus musculus with 2 samples.

How the data were processed

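Total RNA from mouse mammary cells freshly sorted with an endothelial gate was sequenced as single reads on an Illumina HiSeq instrument, per the labels' protocols. The cells came from adult virgin animals aged 8 weeks and were extracted with Trizol. The gate kept cells negative for lineage markers and positive for CD105, CD31 and Sca1, before the split by Procr. There were 2 libraries, 1 Procr-positive and 1 Procr-negative, grouped by the source named in their labels.

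Reads were mapped uniquely to mm10, per the labels' protocols; the aligner, the counting tool and the gene annotation are not given in the sources used here, nor is any use of strand. The deposited read counts are whole numbers of unique reads per gene, per the file headers, and genes without a read are not listed. The counts summed to the library total in the header for each library. None of the 37 mitochondrially encoded genes of the reference, 9 of them in the oxidative phosphorylation list, was listed in either library. Cells transcribe these genes abundantly, so this is not read as 0 reads, and whether they were annotated or counted is not given in the sources used here. RPKM values were deposited by the authors beside the counts. For every gene they equalled the reads divided by the listed gene length in kb and by that total in M reads, so they carry no information beyond the counts and lengths. The deposited gene lengths differed between the files for 10 genes. Of 17333 genes listed in either library, 15496 were listed in both. Unique mapping drops reads that fit several places, so levels of genes with near-identical copies are underestimates or are split between copies. Reads from overlapping or antisense genes may have been counted for either gene.

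Gene identifiers were looked up in the RefSeq annotation of GRCm38.p6, the assembly behind mm10, for coordinates and current symbols, and 17285 of 17333 (99.7%) matched. Symbols are printed as deposited, with the current one added where it differs. Coordinates are 1-based and span the gene, and the counts are per gene, with no split into exons, introns or UTRs.

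With 1 library per group no test between conditions was possible, and no p-value was computed. The main scale was the log2 ratio of RPKM + 1, Procr-positive over Procr-negative, which understates differences of low genes. Genes with at least 1 RPKM in at least 1 library were kept (12509 genes), and a gene was called higher or lower from 2-fold on this scale. Folds printed for single genes are ratios of RPM (reads scaled to the library total) without a pseudocount. Each has an exact conditional binomial (Clopper-Pearson) 95% interval, given in brackets. Such intervals, and the floor of 3 reads used for a gene without reads, cover counting error only. They leave out the variation between animals, sorts and library preparations, and PCR copies are not independent molecules.

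In advance, 34 gene lists and the rule for named genes were fixed. The rule names Procr, Pecam1, Eng, Ly6a and Ptprc, the 15 genes with the highest and the 15 with the lowest log2 ratio among 8828 genes with at least 5 RPKM and 50 reads in at least 1 library, and the 2 to 4 members of each list with the largest absolute log2 ratio. It gave 150 genes, of which some are not reported here. For each list the text gives the measured members, the number past 2-fold in each direction, the median, and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a p-value. Gene ontology process terms carried by the deposited tables were described in the same way where 10 to 200 genes were measured. Terms with a percentile above 99.9 or under 0.1 were eligible to be named, at most 10 per direction, by the most extreme median. The lists overlap, so counts of different lists are not independent. The progenitor list was drawn from markers reported for vascular progenitors and includes Procr itself, which was used for sorting. Another 6 lists were added after the data were seen and are used only in the closing section.

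The settings varied, as planned before the data were examined, were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 RPKM, centring on the median of all genes, TPM, upper-quartile scaling, RPM with a prior of 1 read, and counts of genes whose counting interval excludes 2-fold. Centring on the pan-endothelial median was added after the data were seen.

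The calculations were tested on simulated data for this comparison, with Poisson reads drawn for 17333 genes at the depths of both libraries. All of 100 genes changed 4-fold passed the 2-fold threshold, as did 30.0% of 100 genes changed exactly 2-fold, which lie on the threshold. Of 11896 unchanged genes, 0.294% passed the 2-fold threshold. Among 13232 genes with 20 or more simulated reads, changed ones included, 95.8% of the counting intervals held the true ratio. Of 100 random lists without a shift, 4.00% fell outside percentiles 2.5 to 97.5, and all of 100 lists shifted 1.5-fold lay above percentile 97.5. The unshifted lists came from the same simulated genes as the lists they were set against, so their share checks the calculation only. Poisson reads hold no biological variation, so these shares cover only counting error and, for the 2-fold calls, the pseudocount. Most simulated genes were unchanged, so simulated list medians spread less than real ones. In the real data, medians of random lists matched to the 20 pan-endothelial genes ran from −0.586 to 0.318 (percentiles 2.5 to 97.5). The share of shifted lists found in the simulation therefore does not carry over to the real lists. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.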

Results

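RNA sequencing was used to compare 2 libraries of cells freshly sorted with an endothelial gate from the mammary gland of adult virgin mice aged 8 weeks. Whether a library pools several animals is not given in the sources used here. Cells were gated as lineage-negative, CD105-positive, CD31-positive and Sca1-positive, and were then split by surface Procr, the endothelial protein C receptor. The labels describe 1 Procr-positive and 1 Procr-negative library, so no difference below has a replicate check and no p-value is given. The Procr-positive library held 9.22 M unique reads on 16247 listed genes, and the Procr-negative library held 9.57 M unique reads on 16582 listed genes. At this depth, 3 reads on a gene of 1 kb corresponded to 0.325 RPKM in the Procr-positive and 0.314 RPKM in the Procr-negative library. The 10 genes with the most reads took 6.64% of reads in the Procr-positive library and 6.02% in the Procr-negative library. In the Procr-negative library the gene with the most reads was Krt8, a keratin of simple epithelia, with 102565 reads.

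The question of the series is how gene expression differs between the Procr-expressing and the remaining vascular endothelial cells of the mammary gland. Procr itself (NCBI gene 19124, a protein-coding gene on chromosome 2, 155751125 to 155755478 in GRCm38) was 8.96-fold higher in the Procr-positive library (95% counting interval 8.57 to 9.38). Its level was 1321 RPKM from 18317 reads against 147 RPKM from 2120 reads. Of the other antigens in the gate, Pecam1 (CD31; chromosome 11, 106654213 to 106715281) was 13.5-fold higher (12.9 to 14.2) and Eng (CD105) 10.3-fold higher (9.72 to 10.9) in the Procr-positive library, although both populations were selected as positive for them. Ly6a, the Sca1 gene, went the other way and was 2.40-fold higher (2.27 to 2.53) in the Procr-negative library, at 486 against 203 RPKM. Ptprc, the pan-leukocyte antigen CD45, was low in both, at 3.37 RPKM in the Procr-positive and 0.920 RPKM in the Procr-negative library. The log2 difference of Procr was 3.16 on the log2(RPKM + 1) scale. It was −0.0083 once log ratios were centred on the pan-endothelial median, a scaling chosen after the data were seen.

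Genes of the pan-endothelial list, meant as general markers of endothelium, were higher in the Procr-positive library throughout. All 20 pan-endothelial genes passed 2-fold, with a median log2 difference of 3.16 (8.96-fold on the RPKM + 1 scale; interquartile range 2.69 to 3.51), which lay at percentile 100 of 10000 expression-matched random lists. The endothelial sialomucin gene Emcn had the highest ratio of this list, at 16.6-fold (14.8 to 18.7; 365 against 22.0 RPKM). Tek, the angiopoietin receptor, was 15.5-fold higher (13.1 to 18.4), the junction gene Esam 12.4-fold higher (11 to 14.0) and the transcription factor gene Sox7 12.7-fold higher (11.2 to 14.3). The lowest ratio in the list was 3.62-fold and the median of the read ratios 9.80-fold. By read ratio Procr lay below 13 and above 7 of the 20 genes, and on the log2(RPKM + 1) scale below 11 and above 9.

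Members of lists below that fell outside the fixed rule for named genes, and are named only to complete a count of 5 or fewer, were chosen after their values were seen. They are Mfsd2a, Esm1, Plau, Myb, Meis1, Mcm3, Pcna, Cdkn1a, Tgfb2, Mmp14, Notch2, Tcf7, Ltbp2, Pdgfc, Fgfr1, F2rl1, Ier3, Myc, Hspa1a, Slc27a4, Cpt1a, Plin2 and Cldn1.

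Markers of single vessel types were also higher in the Procr-positive library, and the venous list held the genes that differed most. Of 18 measured venous genes, 17 were at least 2-fold higher and none was 2-fold lower (median log2 2.86, percentile 100). Of these 18, 6 lay more than 1 log2 unit below the pan-endothelial median. Another 4 lay more than 1 log2 unit above it. These were Selp, which encodes P-selectin (74.0-fold, 69.4 to 78.9; 2151 against 29.1 RPKM), Darc, now named Ackr1 and encoding an atypical chemokine receptor of venules (73.0-fold, 63.4 to 84.4; 1311 against 18.0 RPKM), Sele, which encodes E-selectin (77.6-fold, 67.9 to 89.0; 616 against 7.93 RPKM), and Vwf, the von Willebrand factor gene (24.8-fold, 22.8 to 27.0). Selp and Sele lie close together on chromosome 1, at 164115264 to 164150026 and 164039614 to 164058487, and Darc lies on the same chromosome at 173331886 to 173333503. The median of the venous list minus the pan-endothelial median was −0.30.

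Arterial genes were 2-fold higher in 16 of 22 cases and never 2-fold lower (median log2 2.17, percentile 100, −0.997 from the pan-endothelial median). On the log2(RPKM + 1) scale Bmp4 differed most in this list, at 25.1-fold (17.4 to 37.8), followed by the elastic fibre genes Fbln2 (10.5-fold, 9.85 to 11.3) and Fbln5 (10.7-fold, 9.53 to 12.0) and by Sema3g (8.76-fold, 7.63 to 10.1). Of 19 capillary genes, 15 were higher and 1, Mfsd2a, was lower (median log2 1.95, percentile 100, −1.22 from the pan-endothelial median). The water channel gene Aqp1 was 33.1-fold higher (31.7 to 34.6), the fatty acid translocase gene Cd36 13.0-fold higher (12.4 to 13.6), and Fabp4, with 8691 against 744 RPKM, 11.7-fold higher (11.3 to 12.0). Of 20 tip cell and sprouting genes, 10 were higher and 2, Esm1 and Plau, were lower (median log2 1.27, percentile 100, −1.90 from the pan-endothelial median). Nrp1 was 7.96-fold (7.16 to 8.86) and Angpt2 7.77-fold (6.84 to 8.85) higher. Lymphatic genes showed no such difference: none of 9 was 2-fold higher and 4 were lower (median log2 −0.88, percentile 12.2). The median went from −2.42, as RPM with a prior of 1 read, to −0.50, when centred on the median of all genes. The lower genes were the hyaluronan receptor gene Lyve1, 14.0-fold higher in the Procr-negative library (11.4 to 17.4; 55.3 against 3.95 RPKM), Pdpn (5.58-fold, 3.41 to 9.62), Sema3d and Tbx1, and the last of these had only 2 and 26 reads.

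**Figure D1:**
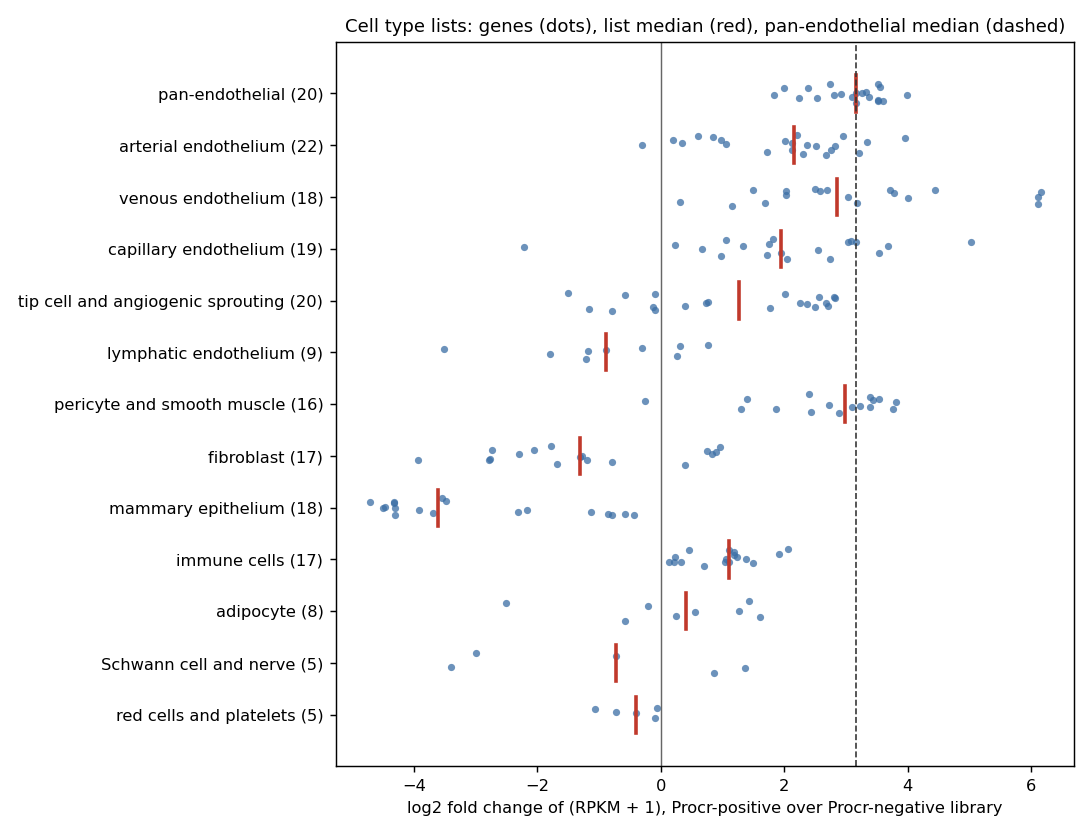
Each dot is 1 measured gene of a cell type list (number of genes in brackets), placed by its log2 difference of RPKM + 1 between the Procr-positive and the Procr-negative library, with the list median as a red bar and the pan-endothelial median of 3.16 as a dashed line. The pan-endothelial and the pericyte genes lie furthest to the right as lists (medians 3.16 and 2.99), and the mammary epithelial genes lie to the left (median −3.61). Of the venous genes, 4 lie more than 1 log2 unit to the right of the dashed line and 6 more than 1 to its left.

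Genes of the mammary epithelium were higher in the library labelled Procr-negative. Of 18 measured epithelial genes, none was 2-fold higher in the Procr-positive library and 14 were lower (median log2 −3.61, percentile 0.00). Krt8 (NCBI gene 16691; chromosome 15, 101996711 to 102004342) reached 5941 RPKM in the Procr-negative against 262 RPKM in the Procr-positive library, a 22.7-fold difference (22.0 to 23.4). Its partner Krt18 was 20.1-fold higher (19.3 to 20.8; 4648 against 232 RPKM), the luminal keratin gene Krt19 26.7-fold higher (25.1 to 28.3; 2061 against 77.3 RPKM), and the epithelial cadherin gene Cdh1 23-fold higher (21.6 to 24.4) in the Procr-negative library. The epithelial list took 2.82% of all reads in the Procr-negative and 0.148% in the Procr-positive library, whereas the pan-endothelial list took 0.0853% and 0.789%. Each gene difference in the following paragraphs stands beside a pan-endothelial median of 3.16 and an epithelial median of −3.61 on the log2 scale.

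Mural cell genes followed the endothelial ones, and their transcripts were abundant in the Procr-positive library. There the pericyte and smooth muscle list summed to 2119 RPKM and the pan-endothelial list to 2894 RPKM. Which cells the mural transcripts came from was not tested. Of 16 pericyte and smooth muscle genes, 15 were at least 2-fold higher in the Procr-positive library and none was 2-fold lower (median log2 2.99, percentile 100, −0.17 from the pan-endothelial median). Vtn was 18.0-fold higher (13.7 to 24.1), the pericyte marker Rgs5 14.7-fold higher (12.8 to 16.9; 187 against 12.8 RPKM), the myosin light chain gene Myl9 11.9-fold higher (10.7 to 13.4) and desmin, Des, 12.5-fold higher (10.4 to 15.1). Fibroblast genes did not follow: none of 17 was 2-fold higher and 11 were lower (median log2 −1.31, percentile 0.01). The proteoglycan genes Dcn and Lum were 16.1-fold (14.4 to 18.2; 287 against 17.8 RPKM) and 8.26-fold (6.54 to 10.6) higher in the Procr-negative library, and Col1a1 was 7.22-fold higher (6.64 to 7.88) there.

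Immune cell genes were mostly at low levels, with 11 of 17 higher in the Procr-positive library and none 2-fold lower (median log2 1.1, percentile 100). Fcer1g rested on 32 and 3 reads (11.1-fold, 3.46 to 56.5), Tyrobp on 55 and 11 reads (5.19-fold, 2.69 to 11), and the macrophage lysozyme gene Lyz2 was 3.03-fold higher (2.36 to 3.91) at 25.8 against 8.51 RPKM. Red cell and platelet genes had 1 of 5, Itga2b, lower and none higher (median log2 −0.40, percentile 51.8). The haemoglobin gene Hba-a1, which shares reads with a near-identical copy, was at 8.39 and 11.4 RPKM. Of 8 adipocyte genes, 3 were higher (Slc2a4, Plin4 and Plin1) and 1, Cidea, was lower (median log2 0.41, percentile 96.7), with 5.53 RPKM as the Procr-positive level of Slc2a4. Of 5 Schwann cell and nerve genes, Ngfr was higher, and Sox10 (21.4 against 1.12 RPKM) and Mbp (35.7 against 3.62 RPKM) were higher in the Procr-negative library instead (median log2 −0.72, percentile 28.7). This median went from −2.99, with only genes of at least 5 RPKM, to −0.23 without a filter.

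Across the transcriptome, 12509 genes reached 1 RPKM in at least 1 library. At 2-fold, 1643 genes (13.1%) were higher and 2964 genes (23.7%) lower in the Procr-positive library, and at 4-fold 604 genes were higher and 762 lower. The median log2 difference of all 12509 genes was −0.38. Higher genes thus made up 35.7% of the 2-fold calls on the deposited scale, against 59.6% (2426 higher, 1644 lower) once log ratios were centred on that median and 50.3% (2097 higher, 2076 lower) with upper-quartile scaling. Centred on the pan-endothelial median, 14 genes were 2-fold higher and 11997 lower.

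The 15 genes furthest above in the Procr-positive library were led by Selp, Darc and Sele. Next came Hdc, which encodes the histamine-forming enzyme histidine decarboxylase, at 58.5-fold (41.7 to 84.8; 87.5 against 1.49 RPKM), followed by Aqp1, by Tmem252 at 40.3-fold (33.0 to 49.9) and by Chp2 at 52.1-fold (32.3 to 89.8). The adenosine-producing ecto-enzyme gene Nt5e (CD73) was 29.9-fold higher (26.2 to 34.2; 201 against 6.72 RPKM), and the G protein subunit gene Gng11 23.5-fold higher (19.8 to 28.2). Vwf, Csf2rb2 (22.0-fold, 19.6 to 24.9), Neurl3 (26.4-fold, 20.1 to 35.4), the aryl hydrocarbon receptor target Cyp1a1 (40.0-fold, 26.0 to 65.0), AU021092 (26.5-fold, 18.1 to 40.5) and the histamine receptor gene Hrh1 (44.7-fold, 29.6 to 70.8) completed the group. Csf2rb2 has a close paralog, Csf2rb, so its reads are uncertain in their assignment.

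The 15 genes furthest below were those higher in the Procr-negative library, and they included several genes of epithelia. Areg, which encodes the growth factor amphiregulin, was 48.8-fold higher there (43.7 to 54.7; 1409 against 28.9 RPKM; chromosome 5, 91139599 to 91148432). The fibrinogen chain genes Fgb and Fgg were 47.5-fold (41.4 to 54.7) and 34.4-fold (30.1 to 39.4) higher, at 680 and 551 RPKM. Keratin genes were represented by Krt7 (33.6-fold, 30.2 to 37.6; 781 RPKM), Krt4 (50.7-fold, 36.7 to 72.3) and Krt6a (41.1-fold, 31.4 to 54.8), the last sharing sequence with paralogs. Wfdc2 (37.0-fold, 31.2 to 44.3; 760 RPKM), Ly6d (38.8-fold, 30.5 to 50.2; 413 RPKM), the cornified envelope gene Sprr1a (50.3-fold, 34.2 to 77.2), the uroplakin gene Upk3a (39.9-fold, 28.7 to 57.2), the water channel gene Aqp3 (37.0-fold, 27.5 to 51.2) and Fam25c (40.1-fold, 23.7 to 73.9) were in the same group. R3hdml was 81.1-fold higher with a wide interval (43.9 to 169.7) from 10 and 841 reads. The scavenger receptor gene Marco had 565 reads in the Procr-negative and 0 in the Procr-positive library, so it was at least 182-fold higher against a floor of 3 reads per library, which is close to the one-sided 95% limit of a count of 0. The two-sided 95% interval, as given for the other genes, is wider and starts at 147-fold.

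**Figure D2:**
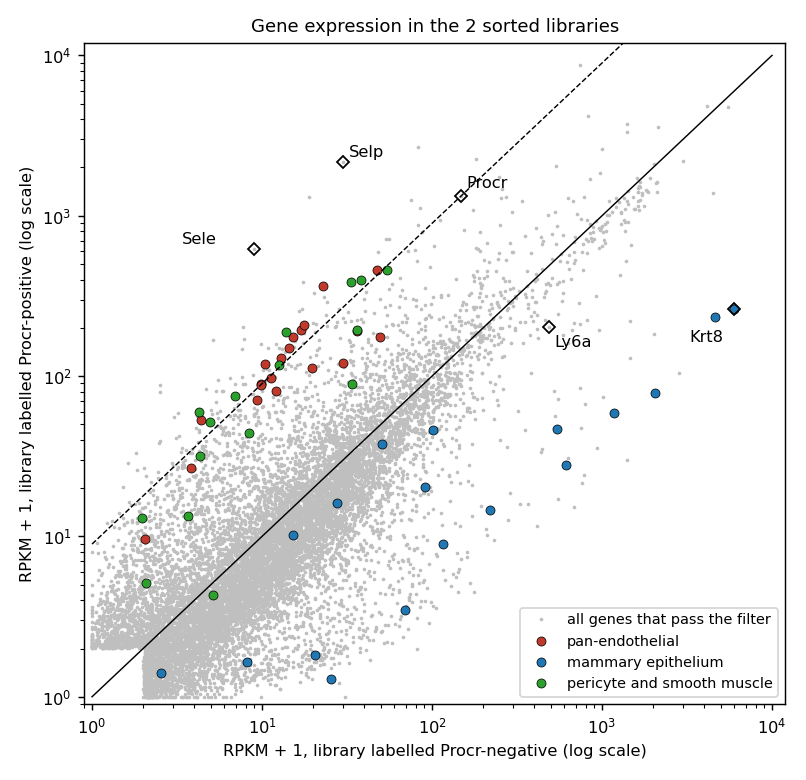
RPKM + 1 of each of the 12509 genes in the Procr-negative (x axis, log scale) and the Procr-positive library (y axis, log scale), with pan-endothelial genes in red, pericyte and smooth muscle genes in green and mammary epithelial genes in blue; the solid line marks equal values and the dashed line the pan-endothelial median of 8.96-fold. Procr lies on the dashed line, Selp (74.0-fold) and Sele (77.6-fold) lie above it, and Krt8 (5941 against 262 RPKM) lies below the solid line.

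Genes of leukocyte recruitment were higher in the Procr-positive library in 11 of 18 cases and 2-fold lower in none (median log2 1.98, percentile 100, −1.19 from the pan-endothelial median). Beside Selp and Sele, the cytokine gene Il6 was 12.5-fold higher (12.0 to 13.1; 2266 against 181 RPKM) and the chemokine gene Cxcl9 11.9-fold higher (10.4 to 13.6). Coagulation and fibrinolysis genes divided, with 7 of 15 higher and 3 lower (median log2 0.70, percentile 99.8, and median 1.33 with only genes of at least 5 RPKM). Vwf, Procr and the inhibitor gene Tfpi2 (17.4-fold, 13.9 to 22.1) were higher, whereas the tissue factor gene F3, the initiator of coagulation, was 27.2-fold higher (25 to 29.5; 935 against 34.4 RPKM) in the Procr-negative library, with Plau and the protease-activated receptor gene F2rl1.

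Lists of vascular signalling genes had medians above 0 and below the pan-endothelial median, and held genes of both directions. In the VEGF, angiopoietin and PDGF list, 9 of 20 were higher and 2, Fgfr1 and Pdgfc, lower (median log2 0.80, percentile 100, −2.36 from the pan-endothelial median). The median was 2.22 with only genes of at least 5 RPKM. Nrp2 was 16.4-fold (14.6 to 18.5), Tie1 12.1-fold (11.1 to 13.2) and Flt1 9.32-fold (8.58 to 10.1) higher. Of 16 Notch pathway genes, 10 were higher and 1, Notch2, was lower (median log2 1.40, percentile 100, −1.76 from the pan-endothelial median). The ligand genes Dll1 and Dll4 were 10.8-fold (9.10 to 12.9) and 4.39-fold (3.85 to 5.02) higher, the glycosyltransferase gene Mfng 11.7-fold (8.43 to 16.7) and the target Hey1 5.19-fold (4.29 to 6.31). In the TGF-beta and BMP list, 11 of 20 were higher and 2, Ltbp2 and Tgfb2, were lower (median log2 1.36, percentile 100, −1.80 from the pan-endothelial median). Bmp4 and Eng led it, followed by the receptor gene Acvrl1 (6.89-fold, 6.18 to 7.71) and the target Id1 (6.43-fold, 5.87 to 7.04).

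Of 16 genes linked to epithelial-mesenchymal transition, 11 were higher and 2, Mmp14 and Tgfb2, were lower (median log2 1.90, percentile 100, −1.27 from the pan-endothelial median). The intermediate filament gene Vim was 6.31-fold higher (6.07 to 6.56; 1089 against 173 RPKM), and the transcription factor genes Tcf4, Twist1 and Zeb1 were 6.98-fold (6.39 to 7.64), 9.19-fold (5.84 to 15.2) and 6.45-fold (5.56 to 7.51) higher. Basement membrane and matrix genes were higher in 13 of 23 cases and lower in 1, Mmp14 (median log2 1.49, percentile 100, −1.68 from the pan-endothelial median). Sparcl1 was 10.7-fold (10.2 to 11.1), the metalloproteinase gene Adamts1 7.76-fold (7.49 to 8.03) and its inhibitor family member Timp3 6.41-fold (6.19 to 6.64) higher. Of 17 genes of fatty acid uptake and PPAR-gamma targets, 10 were higher and 3, Plin2, Slc27a4 and Cpt1a, were lower (median log2 1.33, percentile 100, −1.83 from the pan-endothelial median). Beside Cd36 and Fabp4, the transcription factor genes Meox2 and Tcf15 were 11.5-fold (8.74 to 15.5) and 8.30-fold (5.07 to 14.4) higher.

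Junction genes also divided. Of 15 measured, 7 were higher and 4 lower (median log2 0.88, percentile 99.8). Plvap, which encodes the diaphragm protein of endothelial fenestrae and caveolae, was 16.8-fold higher in the Procr-positive library (15.9 to 17.8; 1248 against 74.2 RPKM). The tight junction genes Ocln, Marveld2 and Cgn were 26.5-fold (21.1 to 33.7), 27.5-fold (20.6 to 37.6) and 28.5-fold (21.0 to 39.8) higher in the Procr-negative library, and Cldn1 was the fourth lower gene.

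**Figure D3:**
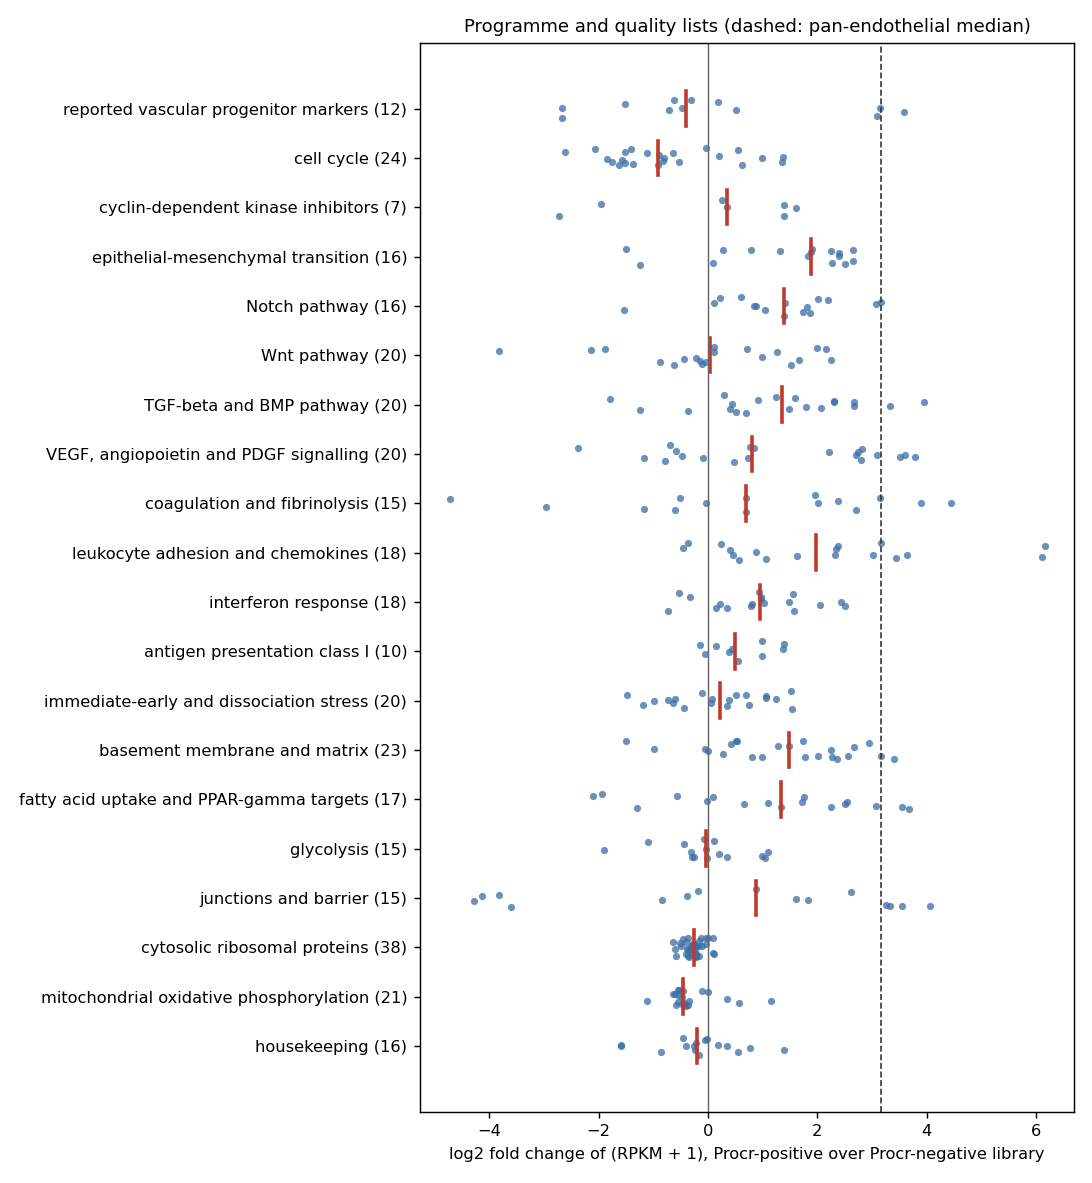
As for the cell type lists, each dot is 1 measured gene of a programme or quality list, placed by its log2 difference of RPKM + 1, with the list median as a red bar and the pan-endothelial median of 3.16 as a dashed line. Every list median lies to the left of the dashed line, from 1.98 for leukocyte adhesion and chemokines down to −0.90 for the cell cycle.

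Genes reported as markers of vascular progenitors did not move together. Of 12 measured, 3 were higher in the Procr-positive library, namely Procr, the transporter gene Abcg2 (12.9-fold, 11.4 to 14.6; 149 against 11.6 RPKM) and Cd34 (8.81-fold, 8.09 to 9.62). Another 3, Runx1, Myb and Meis1, were lower, with Runx1 7.14-fold higher (6.48 to 7.88) in the Procr-negative library; the list median was −0.40 at percentile 39.2. Cell cycle genes were lower in 11 of 24 cases and higher in 2, Mcm3 and Pcna (median log2 −0.90, percentile 1.82). The mitotic genes Ube2c (9.23-fold, 5.31 to 17.3), Ccnb2 (5.62-fold, 3.39 to 9.85) and Ccnb1 (7.63-fold, 4.17 to 15.3) and the replication gene Mcm6 (4.59-fold, 3.97 to 5.32) were higher in the Procr-negative library. Of 7 cyclin-dependent kinase inhibitor genes, Cdkn1c (3.65-fold, 2.76 to 4.89), Cdkn2d and Cdkn1a were higher, and Cdkn2a (3 against 70 reads) and Cdkn2b were lower (median log2 0.35, percentile 94.4).

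The Wnt pathway list had 6 of 20 genes higher and 3 lower, Wnt5a, Rnf43 and Tcf7, and its median of 0.04 (percentile 94.8) went from −0.03, with only genes of at least 5 RPKM, to 0.42, when centred on the median of all genes. The ligand gene Wnt5a was 54.8-fold higher (31.8 to 103.4) in the Procr-negative library, at 17.7 against 0.324 RPKM, while the endothelial receptor genes Fzd4 and Tspan12 were 5.15-fold (4.37 to 6.10) and 5.35-fold (4.51 to 6.39) higher in the Procr-positive library. Of 15 glycolysis genes, Pfkp (2.17-fold, 2.06 to 2.28) and Pfkfb3 (2.07-fold, 1.97 to 2.18) were higher and Hk2 and Tpi1 lower (median log2 −0.04, percentile 58.4), and this median also changed sign with scaling, from −0.04 to 0.34.

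Interferon response genes were higher in the Procr-positive library in 7 of 18 cases and 2-fold lower in none (median log2 0.95, percentile 99.97, −2.21 from the pan-endothelial median). Ifitm3 was 5.69-fold higher (5.39 to 6.0; 1468 against 258 RPKM), Mx2, annotated as a transcribed pseudogene, 6.08-fold (5.12 to 7.26), Isg15 4.23-fold (3.73 to 4.79) and Gbp2 3.01-fold (2.84 to 3.20). Of 10 genes of class I antigen presentation, B2m (2.61-fold, 2.55 to 2.68) and Tap1 (2.65-fold, 2.44 to 2.87) were higher and none was 2-fold lower (median log2 0.50, percentile 94.5). Immediate-early and dissociation stress genes were high in both libraries and took 1.55% of reads in the Procr-positive and 1.5% in the Procr-negative library. Of these 20 genes, 5 were higher (Nr4a1, Socs3, Dusp1, Ier3 and Myc) and 2 lower (Hspa1b and Hspa1a, near-identical copies), with a median log2 of 0.22 at percentile 86.7. Nr4a1 was 2.94-fold higher (2.82 to 3.06) in the Procr-positive library, and Hspa1b was 2.82-fold higher (2.66 to 2.99) in the Procr-negative library.

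Genes that most cells use mostly differed by less than 2-fold. None of 38 cytosolic ribosomal protein genes passed 2-fold in either direction (median log2 −0.25, percentile 2.47), and the median went from −0.25 to 0.13 across the planned settings. The gene furthest from 0 in that list, Rpl11, was 1.55-fold higher (1.5 to 1.61) in the Procr-negative library. Of 21 measured nuclear genes of oxidative phosphorylation, 1 was 2-fold higher and 1 lower in the Procr-positive library, the latter being Uqcrc1, 2.21-fold higher (2.0 to 2.44) in the Procr-negative library (median log2 −0.45, percentile 2.40). Of 16 housekeeping genes, 1, B2m, was higher and 2, among them Actb, were lower (median log2 −0.19, percentile 41.1), with list medians from −0.20 to 0.19 across the planned settings. Actb was 3.0-fold higher (2.92 to 3.08) in the Procr-negative library, at 1283 against 428 RPKM.

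Of 703 gene ontology process terms with 10 to 200 measured genes, 54 had a median in the uppermost 0.1% of random lists and 2 in the lowest 0.1%. The response to protozoan had the highest median of these, with 16 of 18 genes higher (median log2 2.30, −0.87 from the pan-endothelial median), and was led by Il6, Igtp and Gbp9. It was followed by interaction with symbiont (10 of 12 genes higher, 1 lower; median log2 2.05) and the response to interferon-beta (19 of 24 higher, 2 lower; 1.91), whose leading genes included Gbp9, Iigp1 and Gbp4. Defense response to bacterium (22 of 38 higher, 5 lower; 1.21), regulation of blood vessel size (7 of 12 higher, 1 lower; 1.15), positive regulation of T cell differentiation (9 of 16 higher, 1 lower; 1.15), regulation of vasoconstriction (12 of 23 higher, 3 lower; 1.11) and embryonic organ morphogenesis (17 of 33 higher, 8 lower; 1.1) came after them, with 2 terms of ion transporter activity (medians 1.24 and 1.16). In the other direction, regulation of morphogenesis of a branching structure (7 of 12 lower, 1 higher; median log2 −1.90) was led by Cdh1, Wnt5a and Fgfr2, and mammary gland epithelial cell proliferation (8 of 15 lower, 2 higher; −1.25) by Areg, Wnt5a and Esr1. Medians of all upper terms named here lay below the pan-endothelial median, down to −2.06 from it for embryonic organ morphogenesis. The terms of defence, symbionts and interferon-beta share leading genes such as Gbp9 and Gbp4, so they are not independent. Leading genes of a term are those with the largest differences, and so were chosen after their values were seen.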

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

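Centring on the pan-endothelial median was chosen after the results were seen; every other setting here was planned. Leaving out a replicate was not possible, and no paired analysis was possible because each group has 1 library. Procr was higher in the Procr-positive library under every planned setting, from 3.16 to 3.54 on the log2 scale. It was 3.54 when centred on the median of all genes and 3.46 with upper-quartile scaling, shifts that follow from the overall median of −0.38 and from the higher upper quartile in the Procr-negative library. The count of genes 2-fold higher stayed within 1.5 times under all planned settings. The count of lower genes did so under all but centring on the median of all genes, which gave 1644.

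Centred on the pan-endothelial median, 14 genes were 2-fold higher and 11997 lower, as this subtracts 3.16 from every log2 ratio. Procr then came to −0.0083. By the same construction 22 of the 23 list medians above 0 turned negative, and the pan-endothelial median became 0. Those that had been at least 1 came to these values: sorting markers −0.0083, arterial −0.997, venous −0.30, capillary −1.22, tip cell −1.90, pericyte and smooth muscle −0.17, immune −2.06, epithelial-mesenchymal transition −1.27, Notch −1.76, TGF-beta and BMP −1.80, leukocyte adhesion −1.19, basement membrane −1.68, and fatty acid uptake −1.83. Under the planned settings 4 of the 34 list medians changed sign (Wnt, glycolysis, ribosomal proteins and housekeeping). Of 150 named genes 1 did, Pf4, from −0.13 to 0.28 with 14 and 16 reads.

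Depth limits the low genes most. A gene of 1 kb needs about 0.325 RPKM in the Procr-positive and 0.314 RPKM in the Procr-negative library to reach 3 reads, and intervals are wide for genes such as Fcer1g (32 and 3 reads) or Tbx1 (2 and 26 reads). No setting gives the variation between animals or sorts.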

Other observations

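The test of luminal genes not looked at before was written before its result was seen; all other tests in this part, and the 6 added lists, were chosen after the results were seen. Both luminal classes of the mammary epithelium were higher in the library labelled Procr-negative. Of 13 measured genes of hormone-sensing luminal cells, 11 were lower in the Procr-positive library and none higher (median log2 −3.49), among them Areg, Cited1 (208 against 10.1 RPKM) and Prlr (68.2 against 2.47 RPKM). Of 12 luminal progenitor genes, 10 were lower and 1, Cd14, was higher (median log2 −2.92), with Aldh1a3 at 159 against 6.94 RPKM. Basal and myoepithelial genes differed less, with 5 of 10 lower (Krt15, Krt16, Krt17, Lgals7 and Tspan8; median log2 −0.99), and Krt14 was at 49.9 against 36.6 RPKM. Of 10 mesothelial genes, 1 reached 1 RPKM, Gpm6a, with a log2 difference of 0.92.

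Endothelial transcription factor genes were higher in the Procr-positive library in 13 of 13 cases (median log2 2.78), with Gata2 at 35.1 against 3.50 RPKM. The highest log2 difference of this list, 3.53, is that of Sox7, a pan-endothelial gene. As the list overlaps the pan-endothelial one and was made after that result, it is no independent support. Of 16 NF-kappaB-driven genes, 9 were higher and none 2-fold lower (median log2 1.35). Of genes with at least 50 reads in the Procr-positive library, 27 had a counting interval wholly above the highest pan-endothelial ratio of 16.6-fold, including Selp, Sele, Darc, Hdc, Aqp1, Vwf, Bmp4, the neurokinin receptor gene Tacr1 (11.5 against 0.311 RPKM) and the leukotriene receptor gene Cysltr1 (8.07 against 0.0759 RPKM). Genes in this and the previous paragraph beyond the fixed rule were chosen after their values were seen.

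Luminal transcripts were abundant in the library labelled Procr-negative, with Krt8 at 5941, Krt18 at 4648 and Krt19 at 2061 RPKM, although the gate (lineage-negative, CD105-positive, CD31-positive, Sca1-positive) would be expected to remove epithelial cells. Endothelial cells that transcribe epithelial genes beside their usual programme are argued against by the pan-endothelial median of 3.16, although this value was known when the test was chosen. A swap of the libraries stays open, because Procr was 8.96-fold higher in the library labelled Procr-positive but lay at −0.0083 from the pan-endothelial median on the log2(RPKM + 1) scale; a swap would not by itself account for luminal transcripts in a gated library. Luminal epithelial cells in the library labelled Procr-negative may be the source. In the hormone-sensing luminal list given above, 9 genes had values not looked at before this test, and none of them was in a list fixed in advance. Of these, 2 had no usable value (Tnfsf11 with 4 and 1 reads, and Cxcl15, listed in neither library). The other 7 were all lower in the Procr-positive library, with a median log2 of −3.43 (Tbx3 only by −0.022), although 6 of them reached 1 RPKM there. They are among the 13 measured genes of that list, so this test and the list result are not independent. Other luminal genes had already been seen to be lower, so this outcome was likely beforehand. Epithelial transcription by endothelial cells or a wrong file could also give it, so the test cannot tell these from luminal cells. Cells that had replaced an endothelial by an epithelial programme stay open, as the interquartile range of 0.82 of the pan-endothelial log2 ratios does not decide this; a wrong file for the library was not tested, and the difference between Procr-positive and Procr-negative endothelium that the design names cannot be told apart from one in cell makeup with 1 library each.

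Procr differed by about as much as the middle of the pan-endothelial genes. Its log2 difference minus their median was −0.0083 on the log2(RPKM + 1) scale and −0.13 by read ratios, which ranged from 3.62-fold to 16.6-fold over these genes. Whether Procr differs beyond the share of endothelial RNA was not decided by these values, from which the pattern was noticed. Surface Procr, on which the cells were sorted, was not measured by sequencing.

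Selp, Sele and Darc differed by more than the pan-endothelial genes. The lowest counting bound of their log2 read ratios exceeded the highest pan-endothelial ratio by 1.93, but as they were picked for their size and each group has 1 library, this does not decide whether a lower share of endothelial RNA is the whole cause. NF-kappaB activation in the Procr-positive cells could contribute and stays open: the other 15 NF-kappaB-driven genes had a median of −2.09 relative to the pan-endothelial median, but the Procr-negative library also transcribed them, at a median of 66.3 RPKM. A larger venous share among Procr-positive cells also stays open, with the 15 other venous genes at −0.58 relative to the pan-endothelial median and an interquartile range of 1.59. The biological difference between Procr-positive and Procr-negative endothelium named by the design remains untested for these genes.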
